A study of Mus musculus with 16 samples.

How the data were processed

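RNA from mouse colonic mucosa was measured by real-time quantitative PCR on the TaqMan OpenArray Mouse Inflammation Panel, in which each assay runs in its own nanolitre well. The 16 samples fell into 4 groups of 4 by the deposited labels. Healthy mice, given oral buffer (PBS), were the reference. The other groups received dinitrobenzene sulfonic acid (DNBS), a hapten that causes colitis when given into the rectum. They received it with oral PBS (the DNBS group), with the oral bacterium abbreviated CEC in the labels, or with the oral probiotic Escherichia coli strain Nissle. The labels do not spell out CEC. The series description speaks of equal amounts of RNA from each mouse being pooled before measurement, while every sample carries its own number, so it is open whether a sample is 1 mouse or a pool. The p-values below therefore measure only the spread between samples.

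The authors deposited raw cycle thresholds (Ct), with no normalization: the unit, recorded as other, is the PCR cycle at which the fluorescence of an assay crosses its threshold, so that 1 cycle less is about a doubling of template, and 40 stands for no amplification. Thresholding software and any filter on amplification quality were not stated. The table held 648 assays for 584 genes, of which 50 had several assays. A Ct above 28 counted as not detected. Between 528 and 564 assays were detected per sample, and the median Ct of detected assays lay between 22.12 and 23.55. The number of molecules behind a Ct is unknown, so no counting interval was computed.

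The table had been edited before deposit in 2 ways. First, 194 values, 1.87% of all 10368, equalled the mean of the other 3 samples of their group within a tolerance of 2e-06, and were read as filled-in gaps. Healthy sample 3 held 57 of them and DNBS_Nissle sample 1 held 61, against at most 12 in any other sample. Second, the digit pair 40 was almost absent from the decimals of values below 40: it occurred 15 times, against a median of 463 for other digit pairs, and it was missing from assay names, so that Cd40 was listed as Cd and Cd40lg as Cdlg. A value that lost this pair after the decimal point can be off by less than 1 cycle. In all, 532 values, 5.52% of those below 40, had 4 or fewer decimals. Both kinds of value were kept and then left out in alternatives.

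Each gene's level was the mean Ct of the reference genes minus the Ct of the gene, written as −ΔCt, a log2 scale on which higher means more RNA. The reference was the mean of 13 genes (19 assays), among them Actb, Gapdh, Gusb, Hprt1, Ipo8, Pgk1, Polr2a, Ppia, Rplp2, Tbp and Ywhaz. Some reference genes, and 1 gene among the samples that stood apart, are not reported here by name. Ywhaz ranged from a Ct of 17.9 to 26.8 and Rplp2 from 23.6 to 26.6, a wider range than the other reference genes. Within groups their SD was 3.47 and 1.01 cycles, against 0.27 to 0.57 for the others used. Both stayed in the main reference, so their spread shifts all −ΔCt values of a sample together. That shift enters the list scores and the correlations between genes within groups. B2m and Tfrc were kept out of the reference and used only in an alternative. The control 18S was not on the panel under that name. Where a gene had several assays, those detected in the most samples were averaged and the others left out. In 36 genes with several usable assays, the lowest correlation between the assays of a gene had a median of 0.76. In 6 of these genes the assays disagreed on the sign of the difference between DNBS and healthy.

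A gene was tested in a comparison when it was detected in at least 3 of 4 samples of both groups. Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in 1 model over the 16 samples with 12 residual degrees of freedom, and adjusted by the Benjamini-Hochberg method over the genes of each of the 6 comparisons, with a threshold of 0.05 on the adjusted p. Standard errors (SE) come from this model, and group means are given with the standard deviation (SD) between samples. Genes detected in at least 3 samples of one group and at most 1 of the other were counted as detection differences and tested with the two-sided Fisher's exact test. For these, the fold is a lower bound against the detection limit, provided that the undetected wells did not fail. A failed well cannot be told from one with little RNA. The comparison of DNBS with healthy was tested on simulated data with the spread of these samples, over 412 genes with 40 changed in each of 20 runs. It recovered 7.8% of genes changed by 1 log2 unit, 74.5% of those changed by 2 and 97.5% of those changed by 4, with 10.1%, 6.1% and 6.4% of the calls false. The median SE of the genes tested in this comparison was 0.47, while that of the changes that passed against healthy was 0.91. These shares therefore do not carry over to genes with a larger spread, for which fewer changes would be recovered.

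Gene lists were tested with fry as the main test, which asks whether the genes of a list move one way on balance, and with camera, which compares a list with the other genes of the panel, using a preset correlation of 0.01 and then an estimated one. The panel itself consists of inflammation genes. The 21 lists were neutrophil recruitment, acute pro-inflammatory cytokines, monocyte and macrophage chemokines, interferon and type 1 response, type 2 response, type 3 response, regulatory cytokines and T cells, T cell markers, B cell markers, myeloid cell markers, mast cell markers, epithelial markers, smooth muscle and nerve markers, endothelial markers and leukocyte adhesion, Toll-like receptor and NF-kappaB pathway, prostaglandin and leukotriene pathway, phospholipases, matrix remodelling and coagulation proteases, MAP kinase pathway, angiogenic and repair growth factors, and the tumour necrosis factor superfamily. The 15 lists with at least 5 tested members were tested. A list score is the mean −ΔCt of its members detected in at least 3 of 4 samples of at least 1 group. Values under the limit were set to the limit, and a member can enter through the group where it is high. Scores were compared with a two-sided exact permutation test, for which 0.0286 is the smallest p that 4 against 4 samples allow. Fry and camera also used values set to the limit, while the medians beside them come from fits of detected values.

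Whether an oral strain moved genes back towards healthy was measured as a correlation across 412 genes detected in all samples, with the DNBS samples split so that the compared changes share none of them. Genes are not independent replicates, so a permutation of sample labels gave its p. Sample numbers recur between groups, but the correlations between samples with a common number, after taking off the group means, had no common sign (10 pairs, from −0.474 to 0.305), so they were not treated as pairs.

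The groups, comparisons, tests, thresholds, lists, reference genes and the rule for naming genes were fixed before the data were examined. The rule named, per comparison, up to 12 passing genes with the largest change each way, the genes with the lowest p up to 10 where fewer passed, the 6 detection differences with the largest bound each way, up to 4 genes per tested list, and a fixed set of cytokines and related genes (Il1b, Il6, Tnf, Ifng, Il17a, Il10, Nos2, Ptgs2, Cxcl1, Cxcl2, Ccl2, Tlr4 and Tgfb1). Genes outside the rule are named only where the text says that they were chosen after their values were seen. Genes are named by the symbols of the table, with a current symbol added where it differs. Alternatives fixed at the same time were the global mean, all endogenous controls, the 3 most stable reference genes or Gapdh alone as reference, quantile normalization, detection limits of Ct 26 and of any Ct under 40, undetected values set to the limit, detection in all samples, a fit of only the groups compared, a trended and robust variance, the sample number as a replicate block, and leaving out each sample for the counts of genes. Alternatives chosen after seeing the data were reference genes without Ywhaz and Rplp2, filled values set missing, values with 4 or fewer decimals set missing, no single-exon assays, no healthy sample 3 and DNBS_Nissle sample 1, and leaving out each sample for the list tests, the named genes and the bounds of detection differences. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.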

Results

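The panel read 648 assays in 16 samples of colonic mucosa: 4 from healthy mice, 4 from mice given DNBS, 4 given DNBS and oral CEC, and 4 given DNBS and oral Nissle. Detected assays averaged 535 ± 5.0 in healthy samples, 557 ± 4.5 in DNBS, 552 ± 4.8 in DNBS_CEC and 558.2 ± 6.2 in DNBS_Nissle (mean ± SD, n = 4 per group). The mean Ct of the reference genes was 19.58 ± 0.37, 19.36 ± 0.43, 19.3 ± 0.30 and 19.07 ± 0.47 in the same order. The first principal component of 412 genes detected in all samples held 33.8% of the variance. Healthy samples lay between −15.85 and −7.36 on it, DNBS samples between −2.75 and 14.71, DNBS_CEC samples between −9.44 and 9.26, and DNBS_Nissle samples between 3.99 and 13.88.

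The comparison of DNBS with healthy mucosa asked what the hapten did. S100a8 and S100a9, the subunits of calprotectin that neutrophils carry in bulk, rose by 6.49 ± 1.5 and 6.23 ± 1.41 on the log2 scale (± SE, n = 4 per group), or 89.7-fold and 75.3-fold. Without DNBS sample 3 they were at 5.17 and 4.86, and without DNBS sample 4 at 7.30 and 7.16. The chitinase-like lectin Chi3l3, now Chil3 (5.34 ± 1.13), the iron-binding neutrophil granule protein Ltf (4.32 ± 0.95) and the inducible nitric oxide synthase Nos2 (3.83 ± 0.72) rose with them, with Chi3l3 at 4.58 without DNBS sample 3 and Ltf at 5.13 without DNBS sample 4. In all 5 genes every DNBS sample exceeded every healthy sample.

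Those 5 of 457 tested genes passed, with limma adjusted p from 0.0284 (Nos2) to 0.045 (the other 4), and none fell. At an unadjusted p under 0.05 there were 45 genes, 36 of them higher, against 22.9 expected by chance. In 39 genes (8.5%) the groups did not overlap, where chance gives 2.86%. The count changed when single samples were left out, which also leaves fewer values in the fit, and these effects were not separated. No gene passed without healthy sample 3, healthy sample 4, healthy sample 6, DNBS sample 2 or DNBS sample 3, 1 passed without healthy sample 5, 2 without DNBS sample 5 and 6 without DNBS sample 4. With the global mean or quantile normalization 0 passed, with 3 other choices of reference genes 1, 1 and 5 (all endogenous controls, the 3 most stable and Gapdh alone), and without healthy sample 3 and DNBS_Nissle sample 1, which held most filled values, 0 passed. The 5 genes stayed higher in all of these fits.

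The genes next in rank did not pass. Inhbb, a subunit of activin B, was 3.27-fold higher (limma adjusted p = 0.104), the neutrophil chemokine Cxcl5 6.40-fold (0.104), the haem-degrading enzyme Hmox1 4.04-fold (0.107), the cytokine Il1b 13.1-fold (0.107) and the matrix cytokine Spp1 7.13-fold (0.162). DNBS sample 3 stood apart in Il1b, at 1.5 on the −ΔCt scale with the others between −3.45 and −2.81, and without it Il1b was higher by 2.56 ± 0.82 instead of 3.71 ± 1.02 on the log2 scale (± SE). Among other cytokines and enzymes, Tnf was higher by 1.74 ± 0.77 on the log2 scale, Ccl2 by 1.79 ± 0.72, Cxcl1 by 2.31 ± 0.90, Ptgs2 by 1.55 ± 0.90, Tgfb1 by 0.57 ± 0.43 and Tlr4 by 0.26 ± 0.46 (± SE, none passing). DNBS sample 3 stood apart in Cxcl1 as well, at −1.53 with the others between −4.28 and −4.11, and without it Cxcl1 was higher by 1.65 ± 0.90. The DNBS means of Ptgs2 and Ccl2 leaned on that sample too, as the comparisons with the oral strains show below. Among lower genes, Il15 differed by −0.95 ± 0.35, Il22ra2 by −1.28 ± 0.51 and Il17rb by −1.31 ± 0.53. Il10 was detected in 0 of the 16 samples.

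Some genes were read in DNBS samples and hardly at all in healthy ones. Cxcl3, another neutrophil chemokine, was detected in 4 of 4 against 1 of 4 samples and was at least 17.2-fold higher, Il6 at least 5.78-fold and the neutrophil protease Mmp25 at least 3.24-fold with the same counts. DNBS sample 3 stood apart in Cxcl3, at 0.2 on the −ΔCt scale with the other DNBS samples between −4.98 and −4.22. With single samples left out, the bounds of Cxcl3, Il6 and Mmp25 came down to 7.51-fold, 3.04-fold and 1.98-fold, each without DNBS sample 3, and Cxcl3 came to 32.6-fold without healthy sample 6 and Il6 to 11.2-fold without DNBS sample 5. The adenosine receptor Adora3 was detected in 4 of 4 against 0 of 4. In all, 13 genes differed in detection, 12 of them detected more often in DNBS. The cathelicidin gene Camp, Il22 (listed as Il22;Iltifb), Ptx3, Il12rb2 and Il1f9 were seen in 3 DNBS samples and 0 healthy ones, and Cxcl11 in 0 DNBS and 3 healthy ones; these 6 were chosen after their values were seen. The mean Ct in DNBS samples was 27.8 for Il12rb2 and 28.5 for Cxcl11, close to the limit on either side. With any Ct under 40, no gene named in this paragraph was among the detection differences. With 4 samples per group Fisher's exact test cannot give a p below 0.0286, and the adjusted values started at 0.155.

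Of the 8 tested members of the neutrophil recruitment list, 7 were higher in DNBS, with a median of 2.49. S100a8 and S100a9 passed over all genes, and 5 (these, Cxcl5, Il8rb, now Cxcr2, and Cxcl1) passed when adjusted over the list alone. The list did not pass fry (adjusted p = 0.178). Camera with the preset correlation gave an adjusted p of 1.64e-05, and 0.789 with an estimated correlation. The list score was −6.15 ± 0.52 in healthy and −2.93 ± 1.96 in DNBS samples (mean ± SD, n = 4), with an exact permutation p of 0.0286 that became 0.181 when adjusted over lists. With single samples left out the fry adjusted p was 0.0413 without DNBS sample 4 (median 3.27), 0.222 without DNBS sample 3 (median 1.84) and between 0.0861 and 0.305 without each of the others. The 8 tested acute cytokines had a median of 1.13, 1 passed over all genes and 2 (Nos2 and Il1b) over the list alone (fry adjusted p = 0.178). All 14 myeloid cell markers were higher, with a median of 0.59 and none passing, Itgam by 2.07 ± 0.78 and Itgb2 by 1.20 ± 0.48 (fry adjusted p = 0.309). The camera calls of the acute cytokines and of the myeloid markers (adjusted p = 0.0199 for both) were lost as well, with adjusted p = 0.848 and 0.871 with an estimated correlation.

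The other lists tested with fry showed no passing member between DNBS and healthy mucosa, also when adjusted over the list alone. Of the smaller lists, 1 gene passed when adjusted over the endothelial and adhesion list alone (Selp at 1.76 ± 0.71, limma adjusted p = 0.0473, chosen after its values were seen). The monocyte and macrophage chemokines had a median of 0.47 (fry adjusted p = 0.527), the prostaglandin and leukotriene pathway 0.65 (0.418) and the phospholipases 0.94 (0.412). The type 3 response had a median of −0.18 over 6 tested genes (0.731) and the T cell markers −0.03 (0.833). Il22 was not among those 6, as it was detected in 0 healthy samples. For the interferon and type 1 response, the type 2 response, regulatory cytokines, the Toll-like receptor pathway, MAP kinases, growth factors and the tumour necrosis factor superfamily, the median lay between 0.04 and 0.22 and changed sign under at least 1 other scaling, so no direction is given (fry adjusted p from 0.665 to 0.854). The MAP kinases had a median of 0.12 and a mean of −0.01. The median of all tested genes was 0.12 and moved to −0.12 with the global mean.

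**Figure D1:**
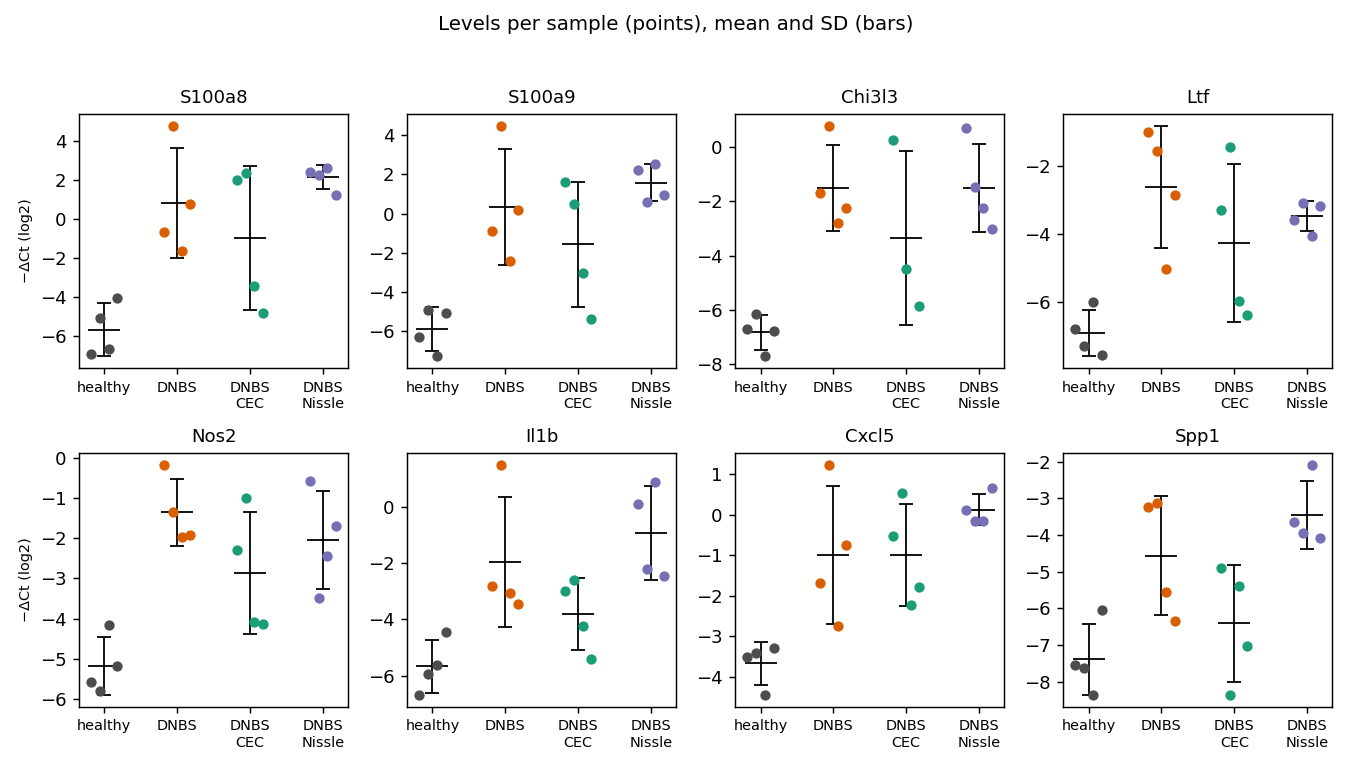
Level (−ΔCt, log2) of 8 genes in each sample (points) of the 4 groups, with the group mean and SD as bars. S100a8 averaged −5.69 in healthy, 0.80 in DNBS, −0.98 in DNBS_CEC and 2.13 in DNBS_Nissle samples.

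The comparison of DNBS_CEC with DNBS asked whether oral CEC altered the inflamed mucosa. None of 474 genes passed in limma (lowest adjusted p = 0.999), and 8 had an unadjusted p under 0.05, against 23.7 expected by chance. The groups did not overlap in 3 genes (0.6%, where chance gives 2.86%). The calls stayed at 0 with each of the 8 samples left out. The median SE of a gene was 0.48, so differences of about 1.01 on the log2 scale to either side remained inside the median 95% confidence interval.

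The lowest p belonged to Clu, a secreted chaperone, at −2.21 ± 0.75 (± SE, n = 4 per group), followed by the tumour necrosis factor family ligand Tnfsf14 at −1.30 ± 0.46, the lipoprotein receptor Lrp8 at 1.06 ± 0.38, the chemokine receptor Ccr1 at −0.95 ± 0.37 and the class I gene H2-Q10 at 1.61 ± 0.63. Nos2 was at −1.52 ± 0.72, Il1b at −1.84 ± 1.03, Spp1 at −1.85 ± 0.84, Tnf at −0.82 ± 0.78, Cxcl1 at −0.92 ± 0.91, Ccl2 at −0.69 ± 0.72, Ptgs2 at −1.16 ± 0.91 and Il6 at −0.30 ± 1.28. Several of these values rested on DNBS sample 3: without it Il1b was at −0.69, Cxcl1 at −0.26, Ptgs2 at −0.29, Ccl2 at −0.26 and Il6 at 0.63, while Nos2 was at −1.52. Without DNBS_CEC sample 8 Cxcl1 was at −0.30. Ifng was detected in 3 of 4 DNBS_CEC and 1 of 4 DNBS samples, and Camp and Il22 in 1 of 4 and 3 of 4. In all, 5 genes differed in detection, with an adjusted p of 0.486 in Fisher's exact test.

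All 9 tested genes of the neutrophil recruitment list were lower in DNBS_CEC than in DNBS, with a median of −1.40 that came to −0.43 without DNBS sample 3 and −0.65 without DNBS_CEC sample 8, and none passed, also when adjusted over the list alone (fry adjusted p = 0.774). Camera with the preset correlation gave 0.0193, and adjusted p = 0.62 with an estimated correlation. S100a9 differed by −1.91 ± 1.43 (−0.54 without DNBS sample 3 and −0.65 without DNBS_CEC sample 8) and Cxcl2 by −2.43 ± 1.48 (−1.19 without DNBS sample 3). The list scores of the 4 DNBS_CEC samples were −2.03, −3.22, −5.30 and −6.14, against −0.03 in DNBS sample 3, −3.51, −3.88 and −4.32 in the other DNBS samples and −6.91 to −5.73 in healthy samples. Of 12 acute cytokines 3 were higher (median −0.65), 0 of 12 monocyte and macrophage chemokines (median −0.63), 1 of 8 genes of the prostaglandin and leukotriene pathway (median −0.61) and 0 of 14 myeloid markers (median −0.28), with fry adjusted p of 0.817, 0.774, 0.774 and 0.774. The T cell markers had a median of 0.20 and the phospholipases 0.41, with fry adjusted p of 0.991 and 0.998, and the phospholipases had a mean of −0.01. None of these members passed. In the other 8 of the 15 lists the sign of the median changed under at least 1 other scaling, and the median of all tested genes moved from −0.09 to between −0.24 and 0.04.

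The comparison of DNBS_Nissle with DNBS asked the same of the probiotic. None of 474 genes passed in limma (lowest adjusted p = 0.995), and 7 had an unadjusted p under 0.05, against 23.7 expected by chance. The groups did not overlap in 5 genes (1.1%, where chance gives 2.86%). The calls stayed at 0 with each of the 8 samples left out. The lowest p belonged to the lipid carrier gene Apoe at −1.47 ± 0.47 (± SE, n = 4 per group), the eosinophil chemokine Ccl24 at 1.26 ± 0.46, the fatty acid binding protein Fabp4 at −1.48 ± 0.56, Lrp8 at 0.99 ± 0.38, the adipokine Retn at −1.88 ± 0.76 and the chemokine receptor Ccr6 at −1.53 ± 0.70.

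Among the cytokines and enzymes, Il1b was at 1.05 ± 1.03 in DNBS_Nissle against DNBS, Il6 at 1.56 ± 1.29, Cxcl1 at 1.02 ± 0.91, Cxcl2 at 0.73 ± 1.48, Nos2 at −0.70 ± 0.72, Tnf at −0.52 ± 0.78, Ptgs2 at 0.67 ± 0.91 and Ccl2 at −0.30 ± 0.72. Without DNBS sample 3 Il1b was at 2.20, Il6 at 2.49, Cxcl1 at 1.68, Cxcl2 at 1.97, Ptgs2 at 1.54 and Ccl2 at 0.12. Without DNBS sample 5 Cxcl2 was at 0.00 and Ptgs2 at −0.06, and without DNBS_Nissle sample 5 Cxcl2 was at −0.15. Cxcl11, a chemokine induced by interferon, was detected in 4 of 4 DNBS_Nissle and 0 of 4 DNBS samples and was at least 3.16-fold higher. Ifng was detected in 4 of 4 against 1 of 4, at least 2.42-fold higher. Il1f10, of the interleukin 1 family, was detected in 1 of 4 against 4 of 4 and was at least 6.49-fold lower. Its mean Ct in DNBS_Nissle samples was 35.9, as the undetected wells stood at 40, so failed amplification there cannot be told from little RNA. Without DNBS_Nissle sample 1 the bounds of Cxcl11 and Ifng were 2.09-fold and 1.34-fold, and without DNBS_Nissle sample 5 that of Il1f10 was 16.6-fold. These were 3 of 7 detection differences, with adjusted p of at least 0.167 in Fisher's exact test.

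All 10 tested neutrophil recruitment genes were higher in DNBS_Nissle than in DNBS, with a median of 1.07 that ranged from 0.51 without DNBS sample 4 to 1.97 without DNBS sample 3, and none passed, also when adjusted over the list alone (fry adjusted p = 0.886). Camera with the preset correlation gave 9.24e-05 for this list and 0.00667 for the acute cytokines (9 of 12 higher, median 0.61), and adjusted p = 0.721 with an estimated correlation for both. Of the 14 myeloid markers 4 were higher (median −0.39), of the 6 tested type 3 genes 1 (median −0.29) and of the 5 phospholipases 2 (median −0.38). Of 12 type 2 genes 9 were higher (median 0.17). The tumour necrosis factor superfamily had a median of 0.03 and a mean of −0.06. All had a fry adjusted p of 0.886, and none of these members passed. In the other 8 of the 15 lists the sign of the median changed under at least 1 other scaling, and the median of all tested genes moved from −0.17 to 0.06 with Gapdh alone.

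The comparison of DNBS_CEC with DNBS_Nissle tested directly whether the oral strains differed. None of 471 genes passed in limma (lowest adjusted p = 0.565), and 21 had an unadjusted p under 0.05, 17 of them lower in DNBS_CEC, against 23.6 expected by chance. The groups did not overlap in 11 genes (2.3%, where chance gives 2.86%). The calls stayed at 0 with each of the 8 samples left out. The lowest p belonged to Ccl24 at −1.80 ± 0.46 (± SE, n = 4 per group), which passed when adjusted over the type 2 list alone (limma adjusted p = 0.0156). Spp1 followed at −2.97 ± 0.84, the neutrophil chemokine receptor Il8rb (Cxcr2) at −2.57 ± 0.80, the adhesion molecule Selp at −2.20 ± 0.71 and Il1b at −2.89 ± 1.03. Selp passed when adjusted over the endothelial and adhesion list alone (0.0138). Cd180, a Toll-like receptor homologue of B cells, was at 1.28 ± 0.46 and the phospholipase Pla2g2d at 1.26 ± 0.52.

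All 9 tested neutrophil recruitment genes were lower in DNBS_CEC than in DNBS_Nissle, with a median of −2.57 (−1.82 without DNBS_CEC sample 8), and none passed, also when adjusted over the list alone (fry adjusted p = 0.583). S100a9 was at −3.16 ± 1.43, Cxcl3 at −2.96 ± 1.28 and Cxcl1 at −1.94 ± 0.91. The differences of S100a9 and Cxcl1 were smaller without DNBS_CEC sample 8, as they were against DNBS. The list score averaged −4.17 ± 1.88 with CEC and −1.95 ± 1.08 with Nissle (mean ± SD, n = 4). Of 12 acute cytokines 1 was higher (median −0.83), of 12 monocyte and macrophage chemokines 2 (median −0.29) and of 13 type 2 genes 3 (median −0.36), with fry adjusted p of 0.583, 0.726 and 0.583. Camera with the preset correlation gave 2.28e-09 for neutrophil recruitment, 1.58e-05 for the acute cytokines, 0.0237 for the chemokines and 0.0343 for the type 2 genes, and adjusted p = 0.314, 0.314, 0.546 and 0.314 with an estimated correlation. T cell markers had a median of 0.45 (fry adjusted p = 0.803), myeloid markers −0.08 (0.908) and the prostaglandin and leukotriene pathway −0.40 (0.849). In the other 8 of the 15 lists the sign of the median changed under at least 1 other scaling, and the median of all tested genes moved from 0.15 to −0.20 with Gapdh alone.

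Detection differed between the strains in 10 genes, in 2 of them as 4 of 4 against 0 of 4 samples. Epo, the gene of erythropoietin, was detected in 4 of 4 DNBS_CEC and 0 of 4 DNBS_Nissle samples and was at least 10.1-fold higher. The mean Ct of Epo was 24.9 in DNBS_CEC samples and 40, no amplification, in DNBS_Nissle samples. Failed wells cannot be told from absent RNA there. Il17a (1 of 4 against 4 of 4), Cxcl11 (0 of 4 against 4 of 4) and Camp (1 of 4 against 4 of 4) were at least 5.47-fold, 3.29-fold and 2.75-fold lower with CEC, and Il1f10 (4 of 4 against 1 of 4) at least 3.84-fold higher. The bound of Epo was 6.74-fold without DNBS_CEC sample 1 and 17.9-fold without DNBS_CEC sample 2, that of Cxcl11 2.18-fold without DNBS_Nissle sample 1, that of Camp 5.65-fold without DNBS_CEC sample 1 and that of Il1f10 9.85-fold without DNBS_Nissle sample 5. The lowest adjusted p of Fisher's exact test was 0.143. Nos2 (−0.82 ± 0.72), Ptgs2 (−1.83 ± 0.91), Tnf (−0.30 ± 0.78), Ifng (−0.41 ± 0.94) and Tgfb1 (−0.05 ± 0.43) did not pass.

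The comparison of DNBS_CEC with healthy mucosa measured how far this group stayed from health. None of 458 genes passed in limma (lowest adjusted p = 0.226), and 25 had an unadjusted p under 0.05, 20 of them higher, against 22.9 expected by chance. The groups did not overlap in 16 genes (3.5%, where chance gives 2.86%). Without DNBS_CEC sample 8 the count was 1. The lowest p belonged to Hif1a, a transcription factor of the response to low oxygen, at 1.62 ± 0.37 (± SE, n = 4 per group). Cxcl5 followed at 2.67 ± 0.71, Lrp8 at 1.37 ± 0.38, thrombopoietin (Thpo) at 1.23 ± 0.38, Apoa1 at −2.32 ± 0.72, Nos2 at 2.31 ± 0.72, the interleukin 22 binding protein Il22ra2 at −1.62 ± 0.51 and the inflammation-resolving protein Anxa1 at 1.18 ± 0.38. S100a8 was 26.1-fold and S100a9 20-fold higher, with wide errors of 1.49 and 1.41 on the log2 scale. The difference of S100a9 was larger without DNBS_CEC sample 8.

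Of the 7 tested neutrophil recruitment genes all were higher in DNBS_CEC than in healthy mucosa, with a median of 1.42 that ranged from 1.06 without DNBS_CEC sample 1 to 2.14 without healthy sample 3. None passed over all genes, and 3 (Cxcl5, S100a8 and S100a9) passed when adjusted over the list alone (fry adjusted p = 0.669). Camera with the preset correlation gave 8.25e-05, and adjusted p = 0.907 with an estimated correlation. Nos2 passed over the acute cytokine list alone (6 of 8 higher, median 0.50, fry adjusted p = 0.949) and Il22ra2 over the type 3 list alone as a lower gene (median −0.18). The Toll-like receptor pathway had 17 of 22 members higher (median 0.24, and between 0.01 and 0.18 under other scalings) and the myeloid markers 12 of 14 (median 0.23, at 0.00 with reference genes without Ywhaz and Rplp2), both with a fry adjusted p of 0.949, and none of their members passed. Cxcl3 and Il6 were detected in 4 of 4 against 1 of 4 samples, at least 5.56-fold (3.15-fold without DNBS_CEC sample 1, 10.6-fold without healthy sample 6) and 4.70-fold higher, and Apoa4 in 1 of 4 against 4 of 4, at least 3.78-fold lower. These were 3 of 12 detection differences, with adjusted p of at least 0.214 in Fisher's exact test. The monocyte and macrophage chemokines had a median of −0.04 and a mean of 0.11 (fry adjusted p = 0.949), and the phospholipases a median of 0.62 (0.669). In 9 of the 15 lists, the myeloid markers among them, the sign of the median changed under at least 1 other scaling, and the median of all tested genes moved from 0.08 to −0.15 with reference genes without Ywhaz and Rplp2.

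The comparison of DNBS_Nissle with healthy mucosa gave the most genes. The neutrophil proteins S100a8 and S100a9 rose 224-fold and 178-fold (7.81 ± 1.5 and 7.48 ± 1.41 on the log2 scale, ± SE, n = 4 per group). Il1b, a main driver of fever and leukocyte recruitment, rose 27.1-fold, the neutrophil chemokine Cxcl5 13.8-fold and its receptor Il8rb (Cxcr2) 15.8-fold. The adhesion molecule Selp, by which vessels catch leukocytes, rose 9.57-fold. Chi3l3 (40.1-fold), Spp1 (15.5-fold), Nos2 (8.76-fold), Inhbb (3.46-fold) and Hif1a (2.82-fold) rose as well. Chi3l3, at 5.33 on the log2 scale, was at 4.59 without DNBS_Nissle sample 1, and Il1b, at 4.76, was at 4.15 without DNBS_Nissle sample 5.

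These were 11 of 457 genes, all higher, with limma adjusted p from 0.012 to 0.0405, and every DNBS_Nissle sample exceeded every healthy sample in each. Lower genes passed only in some alternatives: 5 with quantile normalization, 3 with the global mean, 2 with the 3 most stable reference genes, 1 each with Ct 26, with any Ct under 40 and with undetected values set to Ct 28, 4 in a fit of only these groups, 2 with values of 4 or fewer decimals set missing, 2 without healthy sample 5 and 5 without DNBS_Nissle sample 5. At an unadjusted p under 0.05 there were 77 genes, 42 higher and 35 lower, against 22.9 expected by chance, and in 63 genes (13.8%) the groups did not overlap, where chance gives 2.86%. Chi3l3, Nos2, S100a8 and S100a9 also passed in DNBS against healthy. The count was 0 without healthy sample 3, 3 without DNBS_Nissle sample 1, 7 without healthy sample 4 and 7 without healthy sample 6. It was 4 with a detection limit of Ct 26, 20 in a fit of only these groups, and 0 without both healthy sample 3 and DNBS_Nissle sample 1, which held most filled values. Inhbb passed in 9 of 23 alternatives and Hif1a in 11 of 24. In the direct comparison of the strains 0 genes passed in limma and 21 had an unadjusted p under 0.05, so the larger count with Nissle was not shown to be a difference from CEC.

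Genes just short of passing against healthy were Cxcl1, 10.0-fold higher with Nissle (limma adjusted p = 0.0734), and Il22ra2 at −1.83 ± 0.51 (0.0742), which passed over the type 3 list alone. Il15 was at −1.15 ± 0.35, Pla2g2d at −1.56 ± 0.48 (passing over the phospholipases alone), Ccl7 at 2.98 ± 0.94, Tnfrsf1b at 1.38 ± 0.45, Ptgs2 at 2.21 ± 0.90 and Ccl2 at 1.49 ± 0.72. Cxcl3 and Il6 were detected in 4 of 4 DNBS_Nissle and 1 of 4 healthy samples, at least 43.4-fold and 17.1-fold higher (82.5-fold for Cxcl3 without healthy sample 6, and 7.8-fold and 34.1-fold for Il6 without DNBS_Nissle samples 1 and 7). Camp, Il17a, Ptx3 and the endothelial selectin Sele (chosen after its values were seen) were detected in 4 of 4 against 0 of 4, at least 4.69-fold, 4.54-fold, 3.57-fold and 3.18-fold higher, with Ptx3 at 1.34-fold without DNBS_Nissle sample 1 and at 5.67-fold without DNBS_Nissle sample 4. The transcription factor gene Cebpb, read by a single-exon assay, and Apoa4 were detected in 1 of 4 against 4 of 4, at least 5.93-fold and 3.95-fold lower. The mean Ct with Nissle was 33.7 for Cebpb and 28.4 for Apoa4, the latter close to the limit of Ct 28. In all, 20 genes differed in detection, 15 of them detected more often with Nissle, with adjusted p of at least 0.143 in Fisher's exact test.

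The neutrophil recruitment list passed fry in this comparison (median 3.56, 7 of 8 higher, fry adjusted p = 0.0359). In it 4 genes passed over all genes and 5 when adjusted over the list alone. Camera gave an adjusted p of 2.81e-08, and adjusted p = 0.307 with an estimated correlation. The fry adjusted p was 0.0503 without healthy sample 3, 0.0636 without healthy sample 5, 0.142 without healthy sample 6, 0.139 without DNBS_Nissle sample 1, 0.0573 without sample 4 and 0.0821 without sample 5 of that group. The acute cytokines had a median of 1.25, 6 of 8 higher and 2 passing (Il1b and Nos2), with a fry adjusted p of 0.111. Their camera call (0.00512) was lost, with adjusted p = 0.497 with an estimated correlation. Of the myeloid markers 11 of 14 were higher (median 0.46, fry adjusted p = 0.596), and of the 6 tested type 3 genes 1 (median −0.65, 0.333). The panel held 13 type 3 genes, and Il17a, detected in 4 of 4 against 0 of 4 samples, was not among those tested. The type 3 score, which includes Il17a, differed by −0.325. The T cell markers had a median of −0.32 (0.788), the monocyte and macrophage chemokines 0.25 (0.723), the type 2 genes 0.30 (0.596), the phospholipases 0.52 (0.596), the Toll-like receptor pathway 0.12 (0.833, median from 0.01 to 0.30 under other scalings) and the tumour necrosis factor superfamily 0.17 (0.788). In the other 5 of the 15 lists the sign of the median changed under at least 1 other scaling, and the median of all tested genes moved from −0.09 to between −0.17 and 0.08.

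**Figure D2:**
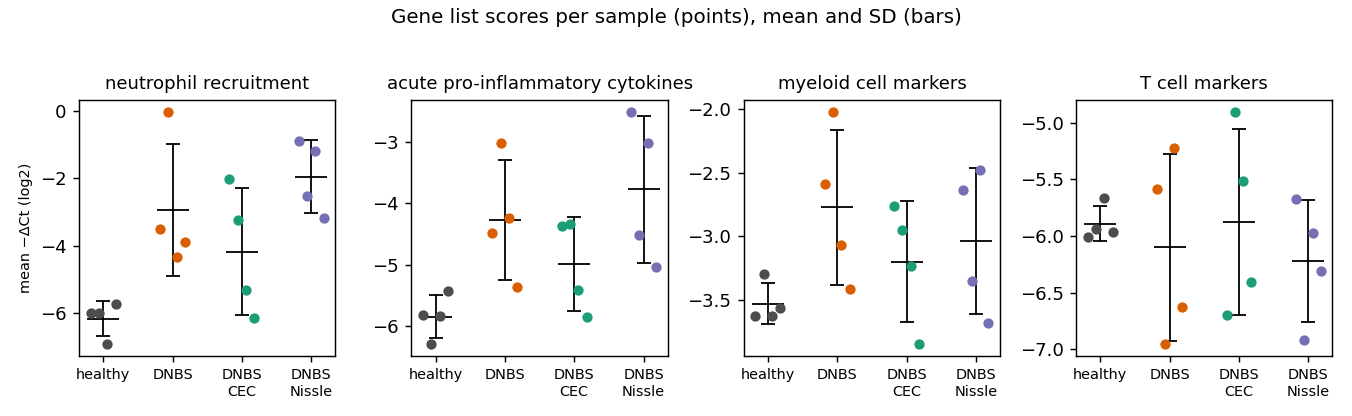
Mean −ΔCt (log2) of the members of 4 gene lists in each sample (points), with the group mean and SD as bars. The neutrophil recruitment score averaged −6.15 in healthy, −2.93 in DNBS, −4.17 in DNBS_CEC and −1.95 in DNBS_Nissle samples, and the T cell score −5.89, −6.10, −5.88 and −6.22.

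Some smaller lists, with fewer than 5 tested members, were read as scores (mean ± SD, n = 4 per group). The 3 epithelial markers (F11r, Il22ra1 and Krt8) averaged 0.69 ± 0.43 in healthy, 0.50 ± 0.60 in DNBS, 0.84 ± 0.37 in DNBS_CEC and 0.38 ± 0.51 in DNBS_Nissle samples. Of the 17 genes of the mast cell list, 4 were on the panel and 3 (Kit, Kitl and Hrh1) entered its score. It averaged −1.79 ± 0.23, −2.15 ± 0.66, −2.29 ± 0.54 and −2.31 ± 0.57, and is not read as a measure of mast cells. The endothelial and adhesion genes averaged −6.61 ± 0.25, −5.56 ± 0.98, −6.08 ± 0.55 and −4.84 ± 0.48, and the matrix and coagulation proteases −3.38 ± 0.28, −3.24 ± 0.40, −3.29 ± 0.56 and −3.53 ± 0.73. As the tested members of their lists, Blnk and Cd40 of the B cell list differed between DNBS and healthy by 0.44 ± 0.58 and −0.28 ± 0.56, and Bdkrb2 of the smooth muscle and nerve list differed by −0.04 ± 0.73 (± SE).

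The last question was whether an oral strain moved genes back towards healthy. Across 412 genes, the change from DNBS to DNBS_CEC and the change from healthy to DNBS had a correlation of −0.296 with the DNBS samples split between them (range −0.546 to 0.0112 over the splits, permutation p = 0.371). With shared DNBS samples it was −0.622, against −0.265 in simulated data without any effect, in which genes varied independently. For Nissle the split value was 0.219 (−0.121 to 0.534, permutation p = 0.429) and the shared value 0.122, with −0.263 in simulated data. With a detection limit of Ct 26 the shared value for Nissle was −0.141 and the split value 0.0775. The changes of the 2 strains against DNBS had a correlation of 0.319 with shared and −0.0113 with split DNBS samples, where simulated data without any effect gave 0.505 for the shared one. The covariance was 0.0817, against 0.158 in simulated data. Random sets of the real genes had a mean correlation within groups of 0.205, unlike the simulated genes. The simulated values therefore do not show how far samples without an effect can differ. Only the permutation p, given for each strain's movement towards healthy, keeps the correlation of the real genes.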

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

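Of the tests below, those of interferon transcription, of filled values behind the spread of inflammatory genes and of noise common to all genes were written down before their results were seen, and the others were chosen after the result was seen.

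A sample was called apart when its gap to the nearest other sample of its group, divided by the range of the group, exceeded Dixon's 95% critical value for 4 samples. Of 642 sets of 4 values of named genes and list scores 30 had such a sample (4.7%), where chance gives about 5%. DNBS sample 3 was apart 5 times, always as the highest: in Il1b (ratio 0.871), Cxcl3 (0.853), Cxcl1 (0.938), Olr1 (0.83) and Osm (0.907). Its Il1b stood at 1.5 on the −ΔCt scale, with the others between −3.45 and −2.81. DNBS sample 2 was highest in Tnf (0.886). DNBS_CEC sample 2 was highest in Socs1 (0.904), Pla2g2e (0.947) and Cxcl9 (0.98) and lowest in Ccr6 (0.847). Its Cxcl9 stood at −0.58, with the others between −4.64 and −4.56. The other DNBS_CEC samples apart were sample 1 as highest in Inhbb (0.883), sample 6 as highest in Bmp2 (0.933) and sample 8 as lowest in Cd180 (0.876).

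Among DNBS_Nissle samples, sample 4 was highest in Inhbb (0.877) and lowest in Map2k3 (0.867) and Mapk8 (0.978), sample 5 was highest in Cd28 (0.861) and Xcr1 (0.861), and sample 7 was lowest in Hif1a (0.834) and Il18 (0.959). Among healthy samples, sample 3 was highest in Ripk2 (0.896), and sample 4 was highest in Itgam (0.87) and Apoa1 (0.843) and lowest in Fos (0.853). Healthy sample 5 was highest in Cd4 (0.865) and Pla2g2d (0.874), and sample 6 was highest in Ccl24 (0.92) and lowest in Ptges (0.876) and Il1rl1 (0.853).

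The first pattern weighed was the set of 16 passing changes of DNBS and DNBS_Nissle against healthy, with a median of 4.15 and a median SE of 0.91. The choice of reference genes was varied over 6 other scalings, under which the median stayed at 4.02 or more. The median of all tested genes moved between −0.12 and 0.12 for DNBS against healthy and between −0.17 and 0.08 for DNBS_Nissle against healthy. Such shifts could not take a median of 4.15 to 0, so this speaks to the size of the changes, not to the calls. The count of DNBS against healthy went from 5 to 0 with the global mean and with quantile normalization. Filled values as the source of all 16 were argued against by 14 of them holding none, although with filled values set missing the count of DNBS_Nissle against healthy went from 11 to 8: Il8rb was no longer tested, and Inhbb (1.79 ± 0.44, then 1.83 ± 0.50) and Hif1a (1.5 ± 0.37, then 1.5 ± 0.39) no longer passed as their SE grew. More neutrophils in the tissue piece is a candidate explanation: 6 neutrophil recruitment genes detected in all samples had a mean correlation within groups of 0.673, against a mean of 0.205 for 10000 random gene sets (permutation p = 9e-04). Cell numbers were not measured, so induction of these genes in other cells stays open.

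The second pattern was that 36 single-exon assays, which can also amplify genomic DNA, varied together within groups. Their mean correlation was 0.481, against a mean of 0.192 for sets of junction assays of the same level (permutation p = 1e-04, the smallest that 10000 sets can give). The high Ct of these assays as the cause was argued against by a highest value of 0.334 among those sets. Interferon transcription that differed between mice was argued against, for the 4 interferon assays it covers, by their mean correlation of 0.073 with 7 interferon response genes, against 0.57 with the other single-exon assays. Genomic DNA carried into the wells may therefore be behind part of these signals. Leaving these assays out gave the count of 5 again for DNBS against healthy and took that of DNBS_Nissle against healthy from 11 to 9. There Inhbb (1.72 ± 0.47) and Hif1a (1.43 ± 0.41) no longer passed. Neither gene was read by a single-exon assay. This alternative also takes single-exon assays out of the reference, so these losses say nothing about genomic DNA.

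The third pattern was a larger spread of 14 inflammatory genes between DNBS samples (median SD 1.24) than between healthy samples (0.63). Filled values as the whole source were argued against by a median log2 ratio of the SDs of 0.7 without them. The SE of the ratio, 0.2, was taken over the 14 genes, so it does not measure the spread between samples. Noise common to all genes of the DNBS samples and mice that reacted to the hapten to different degrees cannot be told apart: what keeps them open is that the ratio of 0.53 in the other genes and that of 0.87 in the inflammatory genes were not separated (permutation p = 0.21). The median SD was 1.27 in DNBS_CEC and 0.94 in DNBS_Nissle samples.

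Other splits of the 8 samples of each comparison were fitted on those samples alone. For DNBS against healthy, 1 of 35 splits, the real one, gave as many as 7 genes, and the highest of the others gave 0. For DNBS_Nissle against healthy, 1 of 35 splits, the real one, gave as many as 20, and the highest of the others gave 1. The share of 0.0286 is the smallest that 35 splits can give and was not adjusted over the 6 comparisons. It argues against chance for each of these counts taken alone, without excluding it. The counts of 5 and 11 from the fit over 16 samples were not tested in this way. For the other 4 comparisons the real count was 0, which all 35 splits reach whatever the grouping, so the splits decide nothing there. The highest other split gave 2 genes for DNBS_CEC against DNBS, 6 for DNBS_Nissle against DNBS, 1 for DNBS_CEC against DNBS_Nissle and 0 for DNBS_CEC against healthy, and whether chance or a structure of the samples other than their groups lies behind the 6 genes stays open.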

How the results depend on the processing

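The alternatives on Ywhaz and Rplp2, filled values, short decimals, single-exon assays and the 2 samples with most filled values, and leaving out single samples for named genes, list tests and detection bounds, were chosen after seeing the data. All passing genes kept their direction in every alternative that tested them, apart from the replicate block, in which single genes were not followed. S100a8 lay between 5.17 and 7.30 in DNBS against healthy (passing in 7 of 24 alternatives, adjusted p from 0.000814 to 0.213 in limma) and Nos2 between 3.44 and 4.17 (passing in 16 of 24, 0.000914 to 0.125). In DNBS_Nissle against healthy S100a8 lay between 7.28 and 8.35 (passing in 22 of 24, 0.000104 to 0.141). These tallies leave out the replicate block, with which no gene of that comparison passed. Of the 5 genes of DNBS against healthy and the 11 of DNBS_Nissle against healthy, 0 passed in all alternatives.

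The count of 5 in DNBS against healthy became 0 with the global mean of all assays and with quantile normalization, 1 with all endogenous controls, with the 3 most stable reference genes and with reference genes without Ywhaz and Rplp2, 1 with a detection limit of Ct 26, with any Ct under 40 and with undetected values set to Ct 28, and 3 with trend and robust. It was 0 without the 2 samples with most filled values, and 0 to 6 with single samples left out. The count of 11 in DNBS_Nissle against healthy became 4 with Ct 26 (3 higher, 1 lower), 20 with only the 2 groups compared (16 higher, 4 lower), 0 without the 2 samples with most filled values, and 0 to 14 with single samples left out. DNBS_CEC against healthy gave 0 to 1 with single samples left out. Without those samples fewer values entered the fits; for the other settings the cause was not tested.

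The count of lists passing fry in DNBS_Nissle against healthy, 1, became 3 with the global mean and with quantile normalization (2 higher, 1 lower), 2 with the 3 most stable reference genes and with Gapdh alone, 0 with Ct 26, with values of 4 or fewer decimals set missing and without the 2 samples with most filled values, and 0 to 2 with single samples left out. In DNBS_CEC against DNBS_Nissle quantile normalization gave 1 list, lower with CEC. In DNBS against healthy 0 to 1 passed with single samples left out. Detection differences in DNBS against healthy, 13 at Ct 28, were 22 at Ct 26 and 4 with any Ct under 40. They were 21 and 3 (from 10) in DNBS_CEC against DNBS_Nissle, 35 and 4 (from 20) in DNBS_Nissle against healthy, and 2 with any Ct under 40 (from 12) in DNBS_CEC against healthy. Of the detection differences named above, only those of Epo and Il1f10 remained with any Ct under 40. The shared correlation of the strains' changes was 0.541 at Ct 26 and 0.136 with any Ct under 40. Simulated data of independent genes without any effect gave 0.494 and 0.496, and split DNBS samples 0.123 and −0.142. The control 18S could not enter the endogenous controls.

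With the sample number as a replicate block, 19 genes passed in DNBS against healthy (18 higher, 1 lower), 2 in DNBS_Nissle against DNBS and 0 in DNBS_Nissle against healthy. Samples of a common number correlated between −0.474 and 0.305 over 10 pairs, without a common sign, and without the block the same samples gave 3, 4 and 0. In the first 2 of these fits 1 standard error was given to all genes, so their counts carry no error of single genes.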

Other observations

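The genes below were chosen after their values were seen. Retn, the gene of resistin, differed between DNBS_Nissle and healthy samples by −2.49 ± 0.75 on the log2 scale (± SE, n = 4 per group, limma adjusted p = 0.121), Adipoq, the gene of adiponectin, by −2.22 ± 0.83 (0.205), Cfd, the gene of adipsin, by −1.93 ± 0.75 (0.208) and Fabp4, the gene of a fatty acid binding protein, by −1.12 ± 0.55 (0.321), none passing. Against DNBS samples Retn differed by −1.88 ± 0.76 and Fabp4 by −1.48 ± 0.56 (0.995 for both). Lep, the gene of leptin, was detected in 0 of 4 DNBS_Nissle samples and in 3 of 4 samples of each other group. Its mean Ct was 28.8 in DNBS_Nissle and 27.6 in DNBS_CEC samples, close to the limit of Ct 28 on either side. With any Ct under 40 Lep was not among the detection differences.

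Epo was detected in 2 healthy, 3 DNBS, 4 DNBS_CEC and 0 DNBS_Nissle samples. Reg3a, an antimicrobial lectin gene of the gut epithelium, stood at 2.94 on the −ΔCt scale in DNBS_Nissle sample 5 and between −8.20 and −5.55 in the other DNBS_Nissle samples.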
